A study of Arabidopsis thaliana with 3 samples.

How the data were processed

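TSN1 crosslink positions were measured by iCLIP2 in 3 biological replicates of Arabidopsis seedlings that expressed a fusion of green fluorescent protein and TSN1. Per the labels' protocols, the fusion protein was captured with GFP-Trap beads, libraries carried sample barcodes and unique molecular identifiers (UMIs), were amplified for 18 PCR cycles and were sequenced as 50 nt single-end reads. The submitters' processing notes name FastQC 0.11.5, STAR 2.7.3a, SAMtools, UMI-tools 1.0, bedtools 2.27.1 and the TAIR10 genome. UMIs separate PCR copies from separate molecules, and reverse transcription stops place the crosslink at single-nucleotide precision. The peak caller and its settings, the merging of replicates and the rule for region labels are not given in the sources used here.

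The 4 deposited files describe the whole series: called peaks, binding sites in 2 formats and target genes. The deposited score of a called peak was, per the file contents, the lowest of the 4 scores written beside it in all 72935 peaks. The deposited score of a binding site equalled the highest called-peak score inside it in all 5673 sites, and every site had a called peak at its centre. Scores have no stated unit and an upper ceiling of 708, reached by 11 called peaks and 4 sites, so they were used only within these lists, to describe, rank, filter and compare sites, and a log2 ratio of scores is not a fold of crosslinking. The number of binding sites per target gene, given as a count in the deposited target table, equalled the sites listed for that gene in all 1504 targets. Site numbers in the authors' identifiers run to 7020, of which 1347 are not in the list. Read depth per library is unknown here, and no deposited value belongs to a single replicate, so no interval here covers variation between replicates. Precision is given as Wilson 95% intervals of shares of sites or called peaks, exact 95% intervals of odds ratios and an SD over genes.

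Region labels, gene types and gene symbols were taken from the authors' annotated table, and coordinates are 1-based TAIR10 positions from the same table. No genome sequence or exon model was used. A reference table of gene spans of TAIR10.1 matched 1468 of 1504 target identifiers, and 5322 of 5331 nuclear gene-assigned sites (99.8%) lay inside the span of their own gene. Those spans were therefore used to assign nuclear called peaks to genes and to place sites along the gene, and none of their coordinates is printed. Of 71311 nuclear called peaks, 68246 fell in exactly 1 protein-coding span, 1569 in several and 1496 in none, and the last 2 kinds were left out of gene counts.

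Shares were counts with Wilson intervals. Called peaks inside sites were compared by Fisher's exact test. The median relative position was compared with 1000 draws of even positions, in place of the planned draws within spliced regions. Median log2 scores of 3' UTR, intron and 5' UTR sites were compared with CDS sites by permutation tests with 100000 resamples. Gene lists were tested by Fisher's exact test with genes that had a called peak as the background, and sites per gene by permutation of mean log2 site number. All tests were two-sided with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. P-values over sites or genes describe these pooled lists and not variation between plants.

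Before the data were examined, 16 lists were fixed by gene identifier and 14 by name patterns. A pattern list was used only if it caught at least 80% of the targets whose descriptions match it, which left aquaporins and the expansins with xyloglucan endotransglucosylases, so 18 lists were used and 12 pattern lists were not. The aquaporin pattern also caught AQI, BRX and CIPK15, and the list was kept as fixed and tested again without them. The naming rule, also fixed in advance, took the 10 targets with the highest summed score, the 10 with the most sites, and TSN1, TSN2, GRP7, GRP8 and GA20OX3 whatever their values. It also took the 3 non-coding or organelle genes with the highest summed score, and the 2 members with the most sites of each list that did not pass (4 where it passed). The plastid genes PSBC, PSAB, PSAA and RBCL, RBP45B, BIP2, AQI, BRX, CIPK15 and the genes named only in the closing section were chosen after their values were seen.

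The tests were first tried on simulated data. A list of 36 genes among 1837 with an odds ratio of 10 was called in 82.5% of 200 runs, and unchanged lists beside it in 0.143% of cases. A log2 score shift of 0.5 in 98 intron sites was called in 100% of 40 runs. A 4-fold difference in sites per gene in a list of 9 genes was called in 100% of 40 runs, against 57.5% for a 2-fold difference and 7.5% with no difference. The score and sites-per-gene simulations used an unadjusted p under 0.05, so they overstate how often the adjusted tests would call such differences. Alternatives covered the score threshold, gene weighting, dominant genes, backgrounds, near-identical copies, called peaks per gene and the meaning of the 3' UTR label. Sequence and pairing at sites, shares against random positions within gene models and agreement of replicates were not analysed here. Computation used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.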

Results

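RNA bound in vivo by TSN1 (Tudor staphylococcal nuclease 1, AT5G07350), a protein with nuclease-like and Tudor domains known from stress granules and from the cortical endoplasmic reticulum (ER), was mapped in Arabidopsis thaliana seedlings by iCLIP2. In this assay ultraviolet light joins protein to RNA, the protein is pulled down, and reverse transcription stops at the crosslinked nucleotide. The plants expressed TSN1 fused to green fluorescent protein from its own promoter in the Col-0 background. Seedlings were 14 days old, received 2000 mJ/cm2 at 254 nm, and were collected 10 h after lights on, with most tissue from above ground. There was 1 group of 3 biological replicates and no control sample. The question addressed was therefore which RNAs, and which parts of them, carried crosslinks in the TSN1 pull-down. Without a control, TSN1 crosslinks could not be told apart from background of the pull-down, here and in all results below. The deposited lists pool the replicates: no value per replicate, no read depth and no replicate spread could be given, and intervals below cover counting error of sites only. The lists held 72935 called peaks of 1 nt, 5673 binding sites of 5 nt and 1504 target genes, all in TAIR10 coordinates. Binding-site scores, which are the authors' own value per site, had a median of 12.5 (quartiles 8.24 and 19.1), and the highest was 708.

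Messenger RNA was the main class of RNA among the binding sites. Protein-coding genes held 5295 of the 5673 binding sites (93.3%, Wilson 95% interval 92.7 to 94.0) and made up 1403 of the 1504 targets. Transfer RNA genes held 77 sites (1.36%, 1.09 to 1.69), the spliceosomal small nuclear RNAs (snRNAs) 23, small nucleolar RNAs 12, long non-coding RNAs 8, ribosomal RNA 5 and other non-coding RNAs 2. A further 212 sites lay in no gene and 39 had no gene type. By genome, 5488 sites (96.7%, 96.2 to 97.2) were nuclear, 171 (3.01%, 2.60 to 3.49) plastid and 14 mitochondrial. Among sites above the median score, 90.7% were in protein-coding genes, 2.54% in tRNA genes and 3.77% in the plastid genome.

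Sites in ribosomal and transfer RNA had the highest scores. The 5 sites in the ribosomal RNA gene AT3G41768 (chromosome 3, 14198126 to 14198967) had a median score of 603, and the gene led all targets with a summed score of 3017. Its highest sites were at the score ceiling of 708, so the sum may be cut short. Sites in tRNA genes had a median score of 51.4 (quartiles 24.9 and 95.9), against 12.3 for sites labelled 3' UTR (untranslated region) and 12.1 for sites labelled coding sequence (CDS). The tRNA median was above the 12.3 of all sites in protein-coding genes (permutation test of median log2 score, added after seeing the data, p = 1e-05, the smallest possible). The score has no stated unit, so no fold of binding is read from it. A pair of sites in AT4G39195, a tyrosine tRNA gene (chromosome 4, 18255002 to 18255017), reached the score ceiling of 708 and summed to 1417, and the single site of the arginine tRNA gene AT2G36600 (chromosome 2, 15346192 to 15346196) scored 707. Nuclear tRNA targets comprised 49 genes, led by arginine with 10 genes and serine with 9, and plastid tRNA targets comprised 16. Among the 16 snRNA targets 9 were U2, the snRNA that pairs with the branch point of introns. Transfer RNA, U2 and ribosomal RNA genes exist in near-identical copies, so which copy was bound is uncertain. Neither RNA abundance nor background of the pull-down was measured.

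The plastid genes with the most sites encoded photosystem subunits, while 65 of the 171 plastid sites lay in no gene. PSBA, which encodes the D1 protein of photosystem II, had 9 sites between positions 585 and 1435, all labelled CDS, and a summed score of 833, the third highest among non-coding and organelle genes. PSBC, a photosystem II antenna protein, had 15 sites, the photosystem I core genes PSAB and PSAA had 14 and 8, and RBCL, the large subunit of Rubisco, had 4. Plastid peaks lay inside binding sites more often than nuclear peaks: 382 of 1513 called peaks (25.2%, 23.1 to 27.5) did so, against 12098 of 71311 (17.0%, 16.7 to 17.2; odds ratio 1.65, two-sided Fisher's exact test p = 8.99e-16). With called peaks above the median score alone the odds ratio was 1.44 (Fisher's exact test p = 6.79e-07). Mitochondrial peaks did so in 35 of 111 cases (31.5%, 23.6 to 40.7), so the higher share was not particular to the plastid. Neighbouring called peaks share sites, with a median of 2 peaks per site. The test and intervals treat peaks as independent and so overstate the precision. Called peaks carry no region label in the deposited list, so this comparison was made by genome and not by transcript region.

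Within protein-coding genes, sites labelled 3' UTR were the largest class. The authors' table placed 3547 of 5295 sites (67.0%, Wilson 95% interval 65.7 to 68.2) in 3' UTRs and 1564 (29.5%, 28.3 to 30.8) in CDS. Introns held 98 sites (1.85%, 1.52 to 2.25) and 5' UTRs 82 (1.55%, 1.25 to 1.92). By gene, 651 of 1403 had 3' UTR sites only, 163 had CDS sites only and 522 had both. The label covered long stretches of some genes. Among the 711 genes with at least 2 such sites, these spread over more than 1000 nt in 198. All 24 sites of SNG1, a sinapoyltransferase gene, had the label across 3281 nt, and the 17 so labelled in HA1, a plasma membrane proton ATPase gene, spanned 4161 nt. Of the 2036 3' UTR sites in genes with both labels, 33 lay upstream of a CDS site of the same gene. That order alone does not show where the coding sequence of the main isoform ends. Counting the label only within 500 nt of the most 3' such site of the gene lowered the 3' UTR share to 46.1% (44.7 to 47.4), an alternative chosen after seeing the data. The planned test of these shares against random positions in the same gene needs exon models and was not run, so no enrichment over transcript length is claimed.

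**Figure D1:**
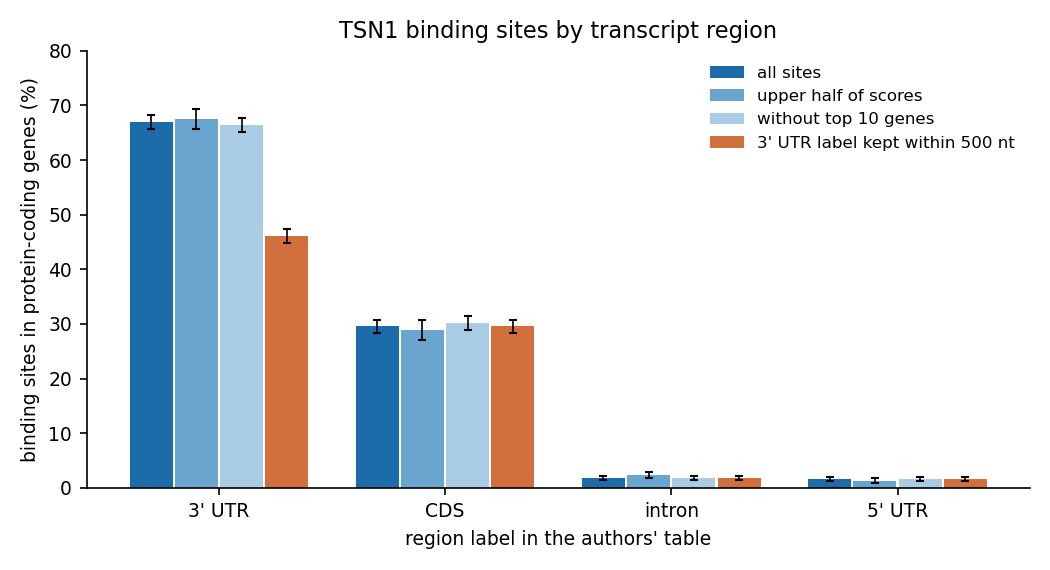
Share of binding sites in protein-coding genes (y axis, percent) by the region label of the authors' table (x axis), for all 5295 sites, for sites above the median score, without the 10 genes with the most sites, and with the 3' UTR label kept only within 500 nt of the most 3' such site of its gene; bars start at 0 and error bars are Wilson 95% intervals. The 3' UTR share was 67.0% over all sites and 46.1% with the restricted label.

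Binding sites lay towards the 3' end of the gene span. Along the gene span, introns included, 5200 nuclear sites of 1376 genes had a median relative position of 0.631, where 0 is the 5' end and 1 the 3' end. The median of random positions lay between 0.477 and 0.521 in 1000 draws (two-sided permutation p = 0.001, the smallest they can give). Positions above 0.75 held 36.4% of sites and positions up to 0.25 held 14.1%. With each gene counted once, the mean position was 0.641 ± 0.199 (SD over 1376 genes), and 1047 genes (76.1%) lay above 0.5 (sign-flip permutation p = 1e-05, the smallest possible with 100000 resamples). The called peaks of the same targets had a median of 0.574. Sites labelled 3' UTR had a median of 0.762, CDS sites 0.304, intron sites 0.447 and 5' UTR sites 0.129. Above 0.75 lay 2.95% of CDS sites. Because the 3' UTR label covered long stretches of some genes, these medians depend on the labelling. No preference for a part of the coding sequence is read from them. Sites of a gene are not independent, and transcript coverage along the gene was not measured.

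**Figure D2:**
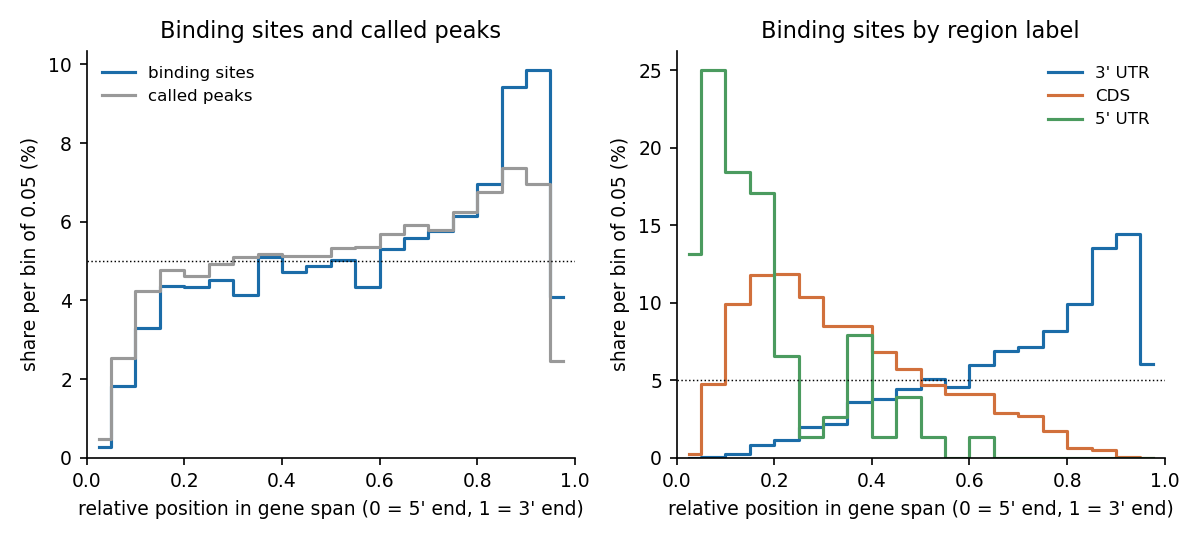
Relative position in the gene span (x axis, 0 at the 5' end and 1 at the 3' end) of binding sites and called peaks of target genes (left) and of binding sites by region label (right), as percent per bin of 0.05 (y axes); the dotted line marks the 5% that even positions would give. Binding sites had a median of 0.631 and called peaks of 0.574. Sites labelled CDS had a median of 0.304 and those labelled 3' UTR of 0.762, values that depend on how far the 3' UTR label reaches upstream.

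Site scores differed little between the labelled parts of the messenger RNA. The median score was 12.3 for 3' UTR sites and 12.1 for CDS sites (log2 ratio 0.02, permutation test, adjusted p = 0.544), and 12.2 for 5' UTR sites (log2 ratio 0.01, adjusted p = 0.931). The 98 intron sites had a median of 14.1 (log2 ratio 0.22 over CDS, permutation test, adjusted p = 0.0568), which did not pass the threshold. Intron sites passed the permutation test when each gene gave 1 median per region (log2 ratio 0.33, adjusted p = 0.00246) and without the 10 genes with the most sites (log2 ratio 0.28, adjusted p = 0.0223). The per-gene test set 72 genes with intron sites against 694 with CDS sites. Intron and CDS sites were not compared within the same gene, so a difference between genes is not separated from one between regions. With 3' UTR sites kept only within 500 nt of the most 3' such site, the log2 ratio over CDS was 0.015 (permutation test, adjusted p = 0.883). That alternative was chosen after seeing the data. These were two-sided tests with 100000 resamples and Benjamini-Hochberg adjustment over 3 regions. Because the 3' UTR label covered long stretches of some genes, the label groups may mix parts of the messenger RNA, which would hide a difference.

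Binding was spread over many genes, most with few sites. Target genes had a median of 2 sites and a mean of 3.61, with 555 genes at 1 site and 104 at 10 or more. The 10 genes with the most sites held 4.68% of all target sites (7.89% when only sites above the median score are counted and ranked), and the 10 with the highest summed score held 12.3% of the summed score. Neighbouring sites of a gene lay a median of 157 nt apart (quartiles 43 and 334).

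BGAL1 (AT3G13750), a beta-galactosidase gene, had the most sites, 36 on chromosome 3 between 4511104 and 4516210, of which 25 were labelled 3' UTR, 9 CDS and 2 5' UTR. ERD6 (AT1G08930), a sugar transporter gene, had 30 sites on chromosome 1 between 2873702 and 2877125. PEN3, an ABC transporter of the plasma membrane, and SHD, the HSP90-type chaperone of the ER, had 27 each. SHM1, the mitochondrial serine hydroxymethyltransferase of photorespiration, had 25, and the aspartic protease gene APA1 and SNG1 had 24 each. TGG1, a myrosinase, had 21, and HA1 and TPC1, a cation channel of the vacuole, had 20 each. By summed score TGG1 led the messenger RNAs with 1417 (chromosome 5, 9079830 to 9082188), ahead of the glycine-rich protein gene GRP3S with 1217 from 5 sites. BGAL1 followed with 1178, the cysteine protease gene RD19 with 1022 from 9 sites, and GRP-3 with 944 from 7. CAB1, a light-harvesting chlorophyll protein with near-identical copies, reached 709 from 5 sites.

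**Figure D3:**
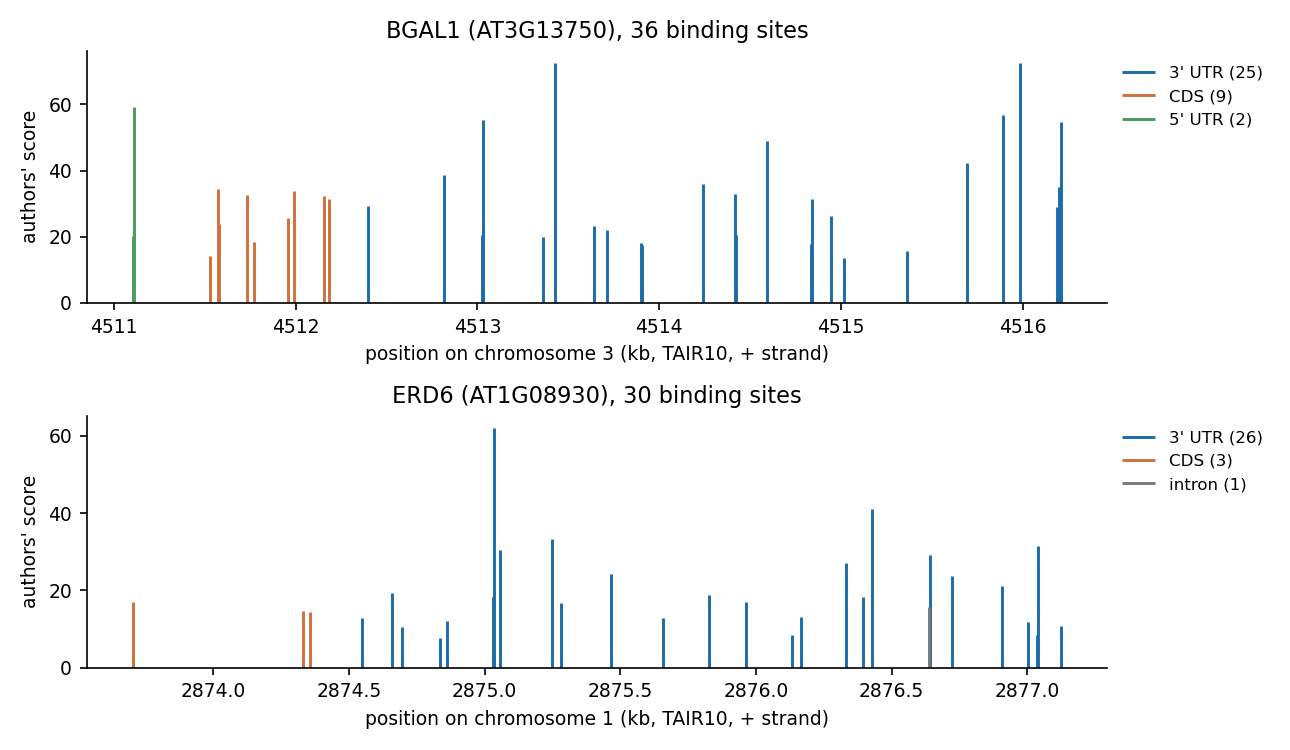
Maps of the binding sites of BGAL1 (top, chromosome 3) and ERD6 (bottom, chromosome 1), with position in kb of the TAIR10 genome on the x axes and the authors' score per site on the y axes; each line is 1 site and its colour is the region label. Of the 36 BGAL1 sites 25 carry the 3' UTR label, and of the 30 ERD6 sites 26 do.

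Gene groups fixed before the data were examined were compared with all protein-coding genes that had at least 1 called peak, 1837 genes of which 1355 (73.8%) were targets. Nearly all members with a called peak were targets in the photosynthesis lists. These were 33 of 36 genes of light harvesting and the photosystems, 16 of 17 of the Calvin cycle and Rubisco, and 14 of 14 of photorespiration and peroxide removal. Of 15 lists with a called member, none passed Fisher's exact test with Benjamini-Hochberg adjustment, and 2 had an unadjusted p under 0.05. Called peaks come from the same pull-down as the sites. The test therefore asks whether genes with peaks also had a site, and cannot show whether TSN1 preferred a gene group. Light harvesting had an odds ratio of 3.98 (exact 95% interval 1.24 to 20.4, adjusted p = 0.178), photorespiration an adjusted p of 0.206 and the Calvin cycle one of 0.280. On simulated data a list of 36 genes with a true odds ratio of 4 was called in 40% of 200 runs, so a change of that size could be missed. Requiring at least 2 sites per target took 5 lists past the threshold. By Fisher's exact test these were light harvesting (29 of 36, adjusted p = 0.000677), the Calvin cycle (16 of 17, adjusted p = 0.000677), photorespiration (14 of 14, adjusted p = 0.000664), ER folding and translocation (9 of 10, adjusted p = 0.0305) and aquaporins (14 of 16, adjusted p = 0.00716). The aquaporin list, made by a name pattern, also held AQI, BRX and CIPK15, which are not aquaporins, and AQI (AT4G38220, an aquaporin interactor with 2 sites) was 1 of the 14. Without these genes, an alternative added after seeing the data, it had 13 of 15 (Fisher's exact test, adjusted p = 0.831, and 0.013 with at least 2 sites per target). Genes with more called peaks have more chances of a site. In a logistic model with the number of called peaks and gene span, fitted for 8 lists, none passed. The model took targets with at least 1 site, as in the main setting, and was not run with at least 2 sites. The log2 odds ratio of light harvesting was 1.80 in the main setting, with 0.5 added to each cell, and 0.89 in the model, without that addition. Those of the Calvin cycle (-0.43), ER folding (-0.65) and aquaporins (-0.53) were positive in the main setting and negative in the model. The measures differ, so these changes are not due to the adjustment alone. The model also adjusts for peaks of the same pull-down. Photorespiration, with no called member outside the targets, could not be fitted. Against all 27444 annotated nuclear protein-coding genes, of which 5.04% were targets, 12 of 18 lists had more targets at an adjusted p under 0.05, a comparison that also follows which genes are expressed, which was not measured.

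Within these lists, photosynthesis genes were represented by PSBP-1, an oxygen-evolving complex subunit with 10 sites (highest score 49.7), and LHCB5, an antenna protein with 9 (highest score 106). For the Calvin cycle GAPB had 16 sites and PGK1 13, and for photorespiration SHM1 had 25 and GLU1, the ferredoxin-dependent glutamate synthase, 20. ER folding and translocation had 9 targets of 10 called members, led by SHD with 27 sites and by the ER chaperone genes BIP1 and BIP2 and the calnexin gene CNX1 with 14 each. BIP1 and BIP2 are near-identical, as are members of the RBCS, LHCB1, EF1A and polyubiquitin families, and their sites are uncertain between copies. Of the HSP70 and HSP90 genes 7 of 9 called members were targets, with SHD, BIP1 and BIP2 again first. The aquaporin list had 14 of 16, or 13 of 15 without the genes that are not aquaporins, with PIP1C at 11 sites and PIP3 at 10, and expansins and xyloglucan endotransglucosylases had 13 of 14, with XTH6 at 10 and EXGT-A3 at 9. Translation factors had 6 of 7, with TCTP at 9 sites and the elongation factor gene AT5G60390 at 8. Polyubiquitins had 4 of 4, with UBQ10 at 12 sites and UBQ3 at 4, and tubulins and actins had 4 of 7, with ACT7 and TUB4 at 3 each.

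Some lists of regulatory and RNA-processing genes held no target, as lists of their size can by chance when 5.04% of all annotated genes are targets. None of 26 stress granule and P-body genes, 20 SR splicing factors, 15 gibberellin genes and 6 SnRK1 kinase subunits was a target, and only 1 of these genes, RBP45B of the stress granule list with 8 peaks, had a called peak. Against all annotated genes none of the 4 lists passed Fisher's exact test (adjusted p = 0.768 for stress granule and P-body genes, with an odds ratio of up to 2.87 in the exact 95% interval, 0.768 for SR splicing factors and 1 for the other 2). Of 20 circadian clock genes 1 was a target, ELF4 with 2 sites. The genes of TSN1 itself and of its paralog TSN2 had no called peak and no site, nor did the gibberellin synthesis gene GA20OX3. The glycine-rich RNA-binding protein gene GRP7 had 2 sites and 64 called peaks, and GRP8, listed under the symbol CCR1, had 1 site and 9 called peaks. Markers of other cell types were present in part. Of 14 root markers 1 was a target, the ER-body beta-glucosidase gene PYK10 with 18 sites (highest score 48.8). Of 10 guard cell, epidermis and phloem markers 4 were targets, led by KCS6 with 14 sites and KCS10 with 11, both genes of very-long-chain fatty acid synthesis.

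**Figure D4:**
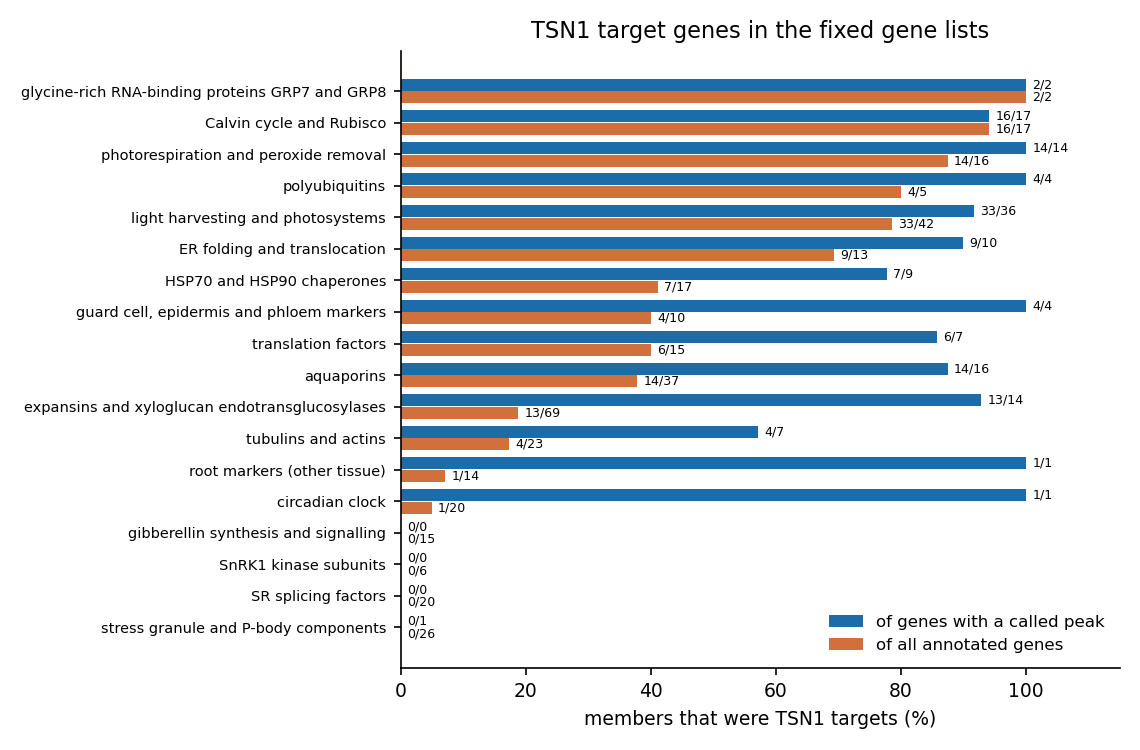
Share of list members that were TSN1 targets (x axis, percent) for the 18 gene lists (y axis), among members with a called peak and among all annotated members, with the counts beside each bar. Light harvesting had 33 of 36 called members and 33 of 42 annotated members as targets, and the SR splicing factors had 0 of 20 annotated members.

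Target genes of several groups carried more sites than other targets, a comparison added after seeing the data. ER folding and translocation targets had a median of 13 sites per gene against 2 in all other nuclear protein-coding targets, a 4.26-fold difference in geometric mean (permutation test, adjusted p = 5.5e-05). By the same permutation test, photorespiration targets had a median of 9.5 sites (3.33-fold, adjusted p = 5.5e-05), the aquaporin list 8 (2.56-fold, adjusted p = 0.000137; 2.80-fold without AQI, adjusted p = 3.67e-05), Calvin cycle genes 7.5 (2.48-fold, adjusted p = 0.00011) and light-harvesting genes 5 (1.65-fold, adjusted p = 0.00117). In these permutation tests HSP70 and HSP90 genes (2.17-fold, adjusted p = 0.0242) and epidermis and phloem markers (2.55-fold, adjusted p = 0.0466) also passed. Expansins and xyloglucan endotransglucosylases (1.5-fold, adjusted p = 0.119), polyubiquitins (1.77-fold, adjusted p = 0.233), translation factors (1.12-fold, adjusted p = 0.756) and tubulins and actins (0.798-fold, adjusted p = 0.679) did not pass the permutation test. These were two-sided permutation tests of mean log2 site number with 100000 resamples, adjusted over 11 lists. ER folding was 2.49-fold per 1000 nt of gene span and 2.28-fold with sites above the median score, and photorespiration 2.22-fold and 1.91-fold. In the same 2 settings the Calvin cycle gave 2.58-fold and 2.33-fold, the aquaporin list 2.63-fold and 2.65-fold, and light harvesting 2.38-fold and 1.80-fold. Per 1000 nt of gene span, the HSP70 and HSP90 genes (adjusted p = 0.531) and the epidermis and phloem markers (adjusted p = 0.069) no longer passed the permutation test. The HSP70 and HSP90 genes also failed the permutation test without the 10 genes with the most sites, SHD among them (adjusted p = 0.159), and without near-identical copies (adjusted p = 0.355), and the epidermis and phloem markers with sites above the median score (adjusted p = 0.0874). Members of these lists also had more called peaks, with a median of 126 in ER folding targets, 93.5 in photorespiration, 90.5 in the Calvin cycle, 70.5 in the aquaporin list and 52 in light harvesting, against 34 in other targets. After regression on the number of called peaks the differences were smaller, and 3 of the 11 lists passed the permutation test: aquaporins (1.59-fold, adjusted p = 0.0044), ER folding (1.49-fold, adjusted p = 0.044) and light harvesting (1.27-fold, adjusted p = 0.0297). Photorespiration (1.31-fold, adjusted p = 0.0967) and the Calvin cycle (1.25-fold, adjusted p = 0.148) no longer passed the permutation test. RNA abundance was not measured, so these comparisons do not separate more RNA from more binding per RNA.

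**Figure D5:**
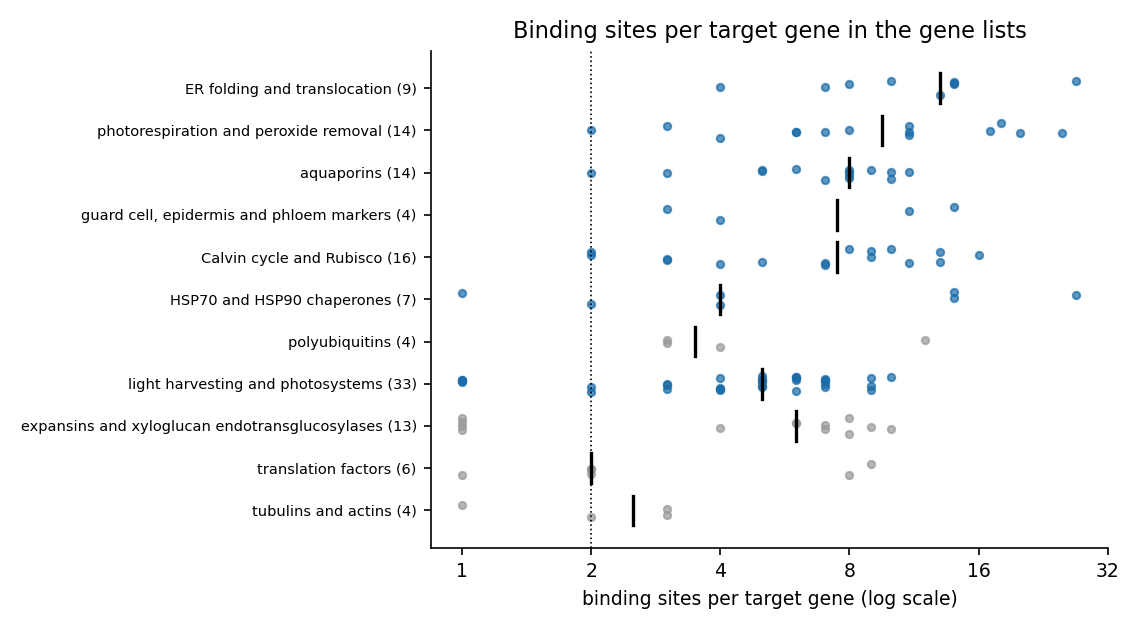
Binding sites per target gene (x axis, log scale) in the 11 gene lists with at least 3 targets (y axis, number of targets in brackets); each point is a gene, the black line is the median of the list and the dotted line the median of 2 sites of other targets, and blue marks lists past an adjusted p of 0.05. The ER folding and translocation genes had a median of 13 sites.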

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

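Of the tests in this part, that of long 3' UTRs and the comparison of the secretory and membrane class were chosen only after the result was seen. Besides the sites in typed genes, the authors' table listed 212 binding sites in no gene and 39 with a gene identifier but no gene type, and both were flagged because they belong to no gene group that the report compares. Because the design has a single group, no biological explanation by a difference between groups of plants was tested for any pattern below.

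The 212 sites outside genes had a median score of 17.5 and a highest score of 363 (chromosome 3, 11586185 to 11586189, plus strand), and 141 were nuclear, 65 plastid and 6 mitochondrial. Transcripts that run past annotated 3' ends would place more of them downstream than upstream of a gene-assigned site. Within 1000 nt, 41 lay downstream and 57 upstream of such a site (two-sided exact binomial p = 0.129), and 41 of 212 is 19.3% (14.6 to 25.2). The rule written beforehand counts that direction against the explanation. The difference did not pass the threshold, however, so the explanation stays open. Of the 141 nuclear sites, 50 (35.5%) lay inside a gene span of the RefSeq table on either strand, 46 of them in protein-coding spans. The strand of those spans was not used, and the share that random positions would give was not computed. The count therefore cannot tell whether genes were missing from the authors' annotation, and antisense transcripts stay open.

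The 39 sites without a gene type lay mostly under identifiers that join several overlapping genes. The largest group was 9 sites under AT3G06355-AT3G06365-AT3G41979 on chromosome 3 between 14201001 and 14203274, with a highest score of 165. They lay downstream, on the same strand, of the sites of the ribosomal RNA gene AT3G41768 (14198126 to 14198967). They are not among the 5 sites counted as ribosomal RNA, and whether they belong to ribosomal RNA was not tested. AT1G05135 held 7 sites and the overlapping plastid genes ATCG00270-ATCG00280 held 5.

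The 3' UTR label spread over more than 1000 nt in 198 genes. Long 3' UTRs bound along their length would keep the label out of the upstream part of the gene. The label reached a relative position under 0.5 in 170 of these genes. In 130 of the 198 the spread exceeded 0.5 of the gene span, which by itself puts a site there. Long 3' UTRs alone would have to take up over 0.5 of the gene in these 130. That argues against them as the only source of the label there, though no exon model was used. In the other 68 the label reached under 0.5 in 40 (58.8%, Wilson 95% interval 47.0 to 69.7), which leaves long 3' UTRs open for those genes. Annotated isoforms with an early stop codon, whose 3' UTR overlaps the coding sequence of the main isoform, predict more such genes where several transcripts are annotated. The spread was seen in 106 of 314 genes with 2 or more RefSeq transcripts (33.8%) and in 92 of 397 genes with 1 (23.2%), a difference of 10.6 percentage points (permutation p = 0.00173). That is consistent with such isoforms contributing, though gene span was not held equal, and the 92 genes with 1 RefSeq transcript leave open another rule of labelling or further isoforms in the annotation the authors used.

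Genes whose descriptions name secretory, vacuolar or membrane proteins, a class drawn up after seeing the data, carried more sites per gene. These 348 targets had a median of 4 sites against 3.5 in the 78 with plastid descriptions and 2 in the remaining 957, a difference of 0.62 in mean log2 sites from all other targets (permutation p = 1e-05, the smallest 100000 resamples can give). Gene length did not account for all of it, as 0.51 remained after regression on gene span (permutation p = 1e-05), and the genes with the most sites did not either, as 0.53 remained without the first 25 (permutation p = 1e-05). After regression on the number of called peaks the difference was 0.0654 (permutation p = 0.13), down from 0.65 in the same genes. More called peaks per gene may reflect more RNA, or more crosslinking per RNA, and with no RNA abundance measured the data do not separate these.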

How the results depend on the processing

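Alternatives for the 3' UTR label, per-gene positions, near-identical copies, the transcription factor and aquaporin lists and sites per gene were chosen after seeing the data. No paired analysis was possible because there is 1 group and the lists pool the replicates, which also rules out leaving out replicates. Settings that need a genome or exon models (other isoforms, exon-only background, sequence, pairing) were not run, and a stricter overlap changes nothing for 1 nt peaks. The cause of the changes below was not tested unless the setting itself names it.

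Among region shares, counting each gene once gave 69.8% for 3' UTR, 27.0% for CDS and 1.36% for intron, sites above the median score gave 2.29% for intron, and the 3' UTR share was 46.1% with the label kept within 500 nt and 55.1% within 1000 nt. Sites above the median score gave 90.7% protein-coding, 2.54% tRNA, 3.77% plastid, and 7.89% of sites in the 10 genes with the most. Score log2 ratios against CDS turned to -0.0627 for 3' UTR with 1 median per gene (permutation test, adjusted p = 0.149) and to -0.00825 for 5' UTR without the 10 genes with the most sites (adjusted p = 0.926), while intron rose to 0.33 and 0.28 in those settings and passed.

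Lists with more targets at an adjusted p under 0.05 numbered 0 in the main setting, 12 against all annotated genes, 11 against these without near-identical copies, 4 with targets above the median score and 5 with at least 2 sites, and 0 with a background of at least 3 called peaks or with a logistic model of called peaks and gene span. Log2 odds ratios of lists that passed no test in the main setting changed sign as follows. Outside the logistic model they had 0.5 added to each cell. Tubulins and actins gave 2.12 against all genes and 2.14 without copies. With at least 3 called peaks, HSP70 and HSP90, circadian clock and root markers gave -0.0021 each, a sign that came from the added 0.5. Without it the odds ratio was 1.16 for HSP70 and HSP90 (7 of 9) and infinite for the others (1 of 1 each). In the logistic model the Calvin cycle gave -0.43, translation factors -0.20, HSP70 and HSP90 -0.29, ER folding -0.65 and aquaporins -0.53, and HSP70 and HSP90 gave -0.34 without copies. Sites per gene of translation factors gave -0.22 per 1000 nt and -0.23 above the median score (log2), and -0.0394 after regression on called peaks.

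The plastid odds ratio and the 3' position kept direction and significance under each alternative run. ER folding, aquaporins and light harvesting kept more sites per gene in each setting. After regression on called peaks the lists past the threshold with more sites per gene fell to 3, and photorespiration and the Calvin cycle no longer passed. Of the other values for single lists, 20 under settings fixed in advance and 13 under added ones newly passed the threshold, each with more targets or sites. In 9 cases, these 2 and 7 for the HSP70 and HSP90 genes or the epidermis and phloem markers, more sites per gene no longer passed.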

Other observations

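All tests in this part were chosen after the values were seen, except where a list was fixed before the data were examined. Ribosomal protein genes formed a large group with few sites each. The target table described 113 targets as ribosomal proteins, with 207 sites and a median of 1 site per gene. The 112 nuclear ones had 1 site in 51.8% of cases against 32.3% of the other 1271 nuclear targets, and 1.72-fold fewer sites in geometric mean (permutation p = 1e-05, the smallest 100000 resamples can give). Their spans were shorter, with a median of 1565 nt against 2062, and per 1000 nt of span the difference was 1.24-fold (permutation p = 0.0104). They also had fewer called peaks, with a median of 19 against 37, and after regression on called peaks the difference was 1.15-fold (permutation p = 0.00336). Histone genes added 7 targets with 15 sites.

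Few transcription factor genes recognised by symbol were targets. Of 306 WRKY, MYB, bHLH, NAC and ERF genes recognised by symbol, 4 had a called peak and 2 were targets, against all annotated genes an odds ratio of 0.123 (exact 95% interval 0.0148 to 0.448, adjusted p = 7.45e-05). Among genes with a called peak, 2 of 4 were targets (odds ratio 0.355, 0.0257 to 4.91, Fisher's exact test, adjusted p = 0.646), so the low share came with few called peaks. The list fixed in advance was not used because its pattern also matched the word superfamily, which alone gave 163 of the 168 targets it found by description. Of the other 5 the symbols caught 2, so the list is not complete. RNA abundance, on which this comparison also depends, was not measured here.

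Of the genes with called peaks, 482 nuclear protein-coding genes had no site, with a median of 7 peaks per gene against 35 in targets. Sites lay close together in places, with 413 of 3918 neighbouring pairs (10.5%) at most 10 nt apart. Among nuclear arginine tRNA targets, 5 of 10 genes had the anticodon TCT. The gene with the longest stretch of 3' UTR labels was GLT1, an NADH-dependent glutamate synthase gene, with 4 such sites over 6149 nt on chromosome 5.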
